A study of Homo sapiens with 2 samples.

How the data were processed

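Total RNA from Calu-3 cells was measured on Affymetrix whole-genome expression arrays, with 1 array from a stretched culture and 1 array from a non-stretched culture. Per the labels' protocols, RNA was purified on Qiagen spin columns and 6 µg of total RNA was turned into biotin-labelled cRNA by the manufacturer's standard procedure. The deposited table holds 1 signal intensity per probe set and array on a linear scale, for 54675 probe sets, of which 62 are control probe sets. The summarisation algorithm, scaling target, detection calls and software behind these intensities are not given in the sources used here. Values ranged from 0.66 to 17518 in the non-stretched array and from 0.70 to 13794 in the stretched array. They are therefore linear and not logarithms.

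The 2 columns were taken as already on one scale. The medians over the 54613 non-control probe sets were 28.7 in the non-stretched and 28.4 in the stretched array, a difference of -0.017 on the log2 scale, which is under the tolerance of 0.1 set for using the values as deposited. The 75th percentiles were 231.1 and 249.0, a log2 difference of 0.11. Hybridisation spike-ins, which are added in equal amounts to each cocktail, had a median log2 difference of -0.11 (range -0.23 to -0.03 over 18 probe sets), so the fold changes carry a scaling uncertainty of about this size.

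Probe sets were named from the platform annotation and gene symbols were updated through the gene ID to RefSeq's current symbols (GRCh38.p14 table, used for names only). A single gene was named for 41037 probe sets with a current symbol and for 54 with the annotation's older symbol, while 1801 listed several genes and 11721 were unnamed here; the last 2 classes entered no gene count. No coordinates are given because the array table names no genome build. A gene was represented by its probe set with the highest mean log2 signal. Probe sets ending in _x_at or _s_at can bind transcripts of related genes, so values of gene families measured by them (metallothioneins, histones) are uncertain.

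Intensities were converted to log2 and values below the 50th percentile of an array were set to that percentile (the floor, 28.7 and 28.4), because no detection calls were used here. A gene was called measured if it exceeded the floor in at least 1 array. Each difference is log2 stretched minus log2 non-stretched. Where 1 of the 2 values lay at the floor, the fold is a lower bound and is written as "at least". With 1 array per group there is no replicate, no SD, no p-value and no test between the conditions; every difference compares these 2 arrays. A gene was counted as higher or lower if it differed at least 2-fold.

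The precision of a single probe set was estimated from the 5818 genes with 2 or more probe sets above the floor in both arrays. The SD of a probe set's log2 difference, from the difference between a gene's 2 brightest probe sets, was 0.36 (0.22 with the floor at the 75th percentile). It covers probe noise and isoform differences but not variation between cultures, labelling reactions or days.

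Before the data were examined, 35 gene lists (739 distinct genes, of which 664 were named on the array and 596 measured) were fixed for an airway epithelial cell line under cyclic stretch, including markers of other cell types. For each list the median log2 difference was set against 10000 random lists of the same size matched on mean expression (20 bins). A list with at least 5 measured members was said to stand apart when its median fell outside the central 95% of the random lists. This percentile describes the 2 arrays and is not a p-value between conditions. If the members of a list varied independently, 1.7 of the 34 lists with enough members would lie outside by chance. Members of a real list can move together, so more could lie outside for any difference between the 2 cultures.

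The genes named in the text were also chosen by a rule fixed beforehand. It took the 12 highest and 12 lowest genes above the floor in both arrays whose measured probe sets all had one sign. It added the 5 brightest genes in each direction that were above the floor in 1 array only and at least 2-fold different, up to 4 members of each list with the largest difference, and the 6 highest and 6 lowest genes for which every one of at least 2 measured probe sets differed at least 2-fold. Genes named outside this rule are marked as such, apart from the ACTB and GAPDH controls and the genes of lists added later.

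The scripts were tested on simulated arrays with the real mean signals, probe noise of the estimated size and 200 changed genes. Over 13111 simulated genes, the count of 2-fold differences recovered 62% of genes changed 2-fold, 94% of those changed 3-fold and 100% of those changed 4-fold, and called 0.51% of unchanged genes. Noise was drawn independently for each probe set from a normal distribution with the same SD at all signal levels. No variation between cultures, labelling reactions or days was simulated. The 0.51% is therefore not the rate of false calls in the real arrays. Of 200 random lists of 20 unchanged genes, 4% stood apart, and 98% of 50 lists shifted by 0.5 on the log2 scale stood higher. The alternatives tried were 3 other normalizations (quantile, centring on the 75th percentile, and removal of an intensity-dependent loess trend), other floors, other ways to combine probe sets, other fold thresholds, and means in place of medians. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.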

Results

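The comparison asks which transcripts differ between airway epithelial cells held under cyclic mechanical strain and cells left unstrained. Calu-3 is a human lung adenocarcinoma line that forms tight epithelial sheets and is widely used as a model of airway surface and gland cells. Cells were grown on flexible collagen-coated plates to about 80% confluence according to the protocol (the design text calls them confluent) in medium with 10% serum. The stretched culture was driven as a sine wave between 0.7% and 20% stretch, 2 s on and 2 s off, for 18 h. The non-stretched culture was labelled with the same 18 h. Each condition was measured on 1 array (n = 1 per group), so the differences below have no replicate check and the number of arrays limits their precision.

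Of 19775 named genes, 13453 were measured and 12185 were above the floor in both arrays. The stretched array had 1046 genes at least 2-fold higher (7.78%) and 1008 at least 2-fold lower (7.49%), 195 at least 4-fold higher and 190 at least 4-fold lower. The median log2 difference of all measured genes was 0.005, and the central 90% of genes lay between -1.23 and 1.24. The log2 signals of the 2 arrays correlated across non-control probe sets with Pearson's r = 0.943; probe sets are not independent replicates. Among 740 genes whose brightest probe set differed at least 2-fold and which had a second probe set above the floor, the second differed in the same direction in 686 (92.7%) and by at least 2-fold in 454 (61.4%). A 2-fold difference is 1 on the log2 scale, against an SD of 0.36 for a single probe set.

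**Figure D1:**
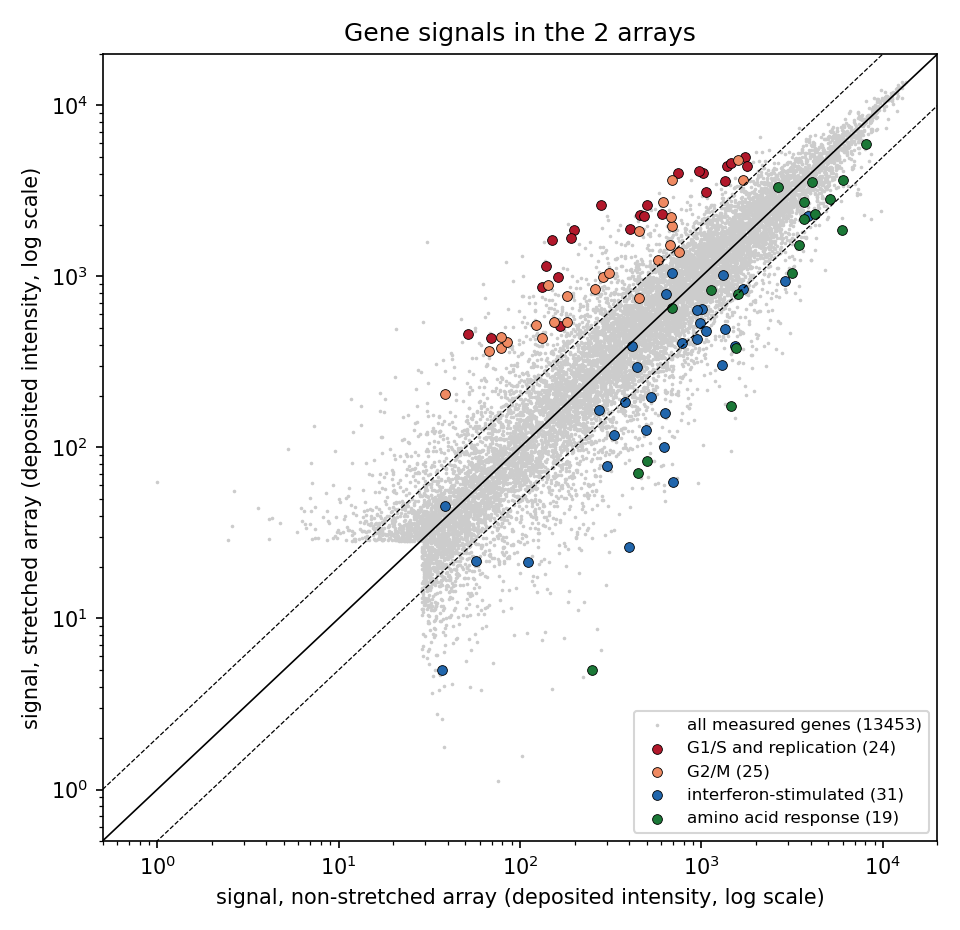
Signal of each measured gene in the non-stretched (x axis) and stretched (y axis) array, both as deposited intensity on log axes; the solid line marks equality and the dashed lines 2-fold differences. All 24 measured G1/S genes (dark red) lie above the upper dashed line, while 18 of 31 interferon-stimulated genes (blue) and 9 of 19 amino acid response genes (green) were at least 2-fold lower; points are drawn as deposited, while folds were counted with the floor.

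The largest difference between genes above the floor in both arrays was in MMP1, the interstitial collagenase, which went from 30.6 in the non-stretched array to 1600 in the stretched array, 52.3-fold higher; its non-stretched signal lay just above the floor and it had 1 probe set. FST, the activin-binding protein follistatin, was 14.4-fold higher, with its 3 probe sets ranging from 1.11 to 3.85 on the log2 scale. FOSL1, an AP-1 subunit, was 12.9-fold higher (102.0 to 1321), and CALB2, the calcium-binding protein calretinin, was 11.8-fold higher. DDC, aromatic amino acid decarboxylase, was 9.70-fold higher and RFLNB was 8.47-fold higher, each with both probe sets above 2.9 on the log2 scale. FAM111B was higher by 3.58 on the log2 scale, STEAP1B was 10.3-fold higher, and DHRS9 was 4.65-fold higher in its brightest probe set. ZNF780B was 18.5-fold higher in one probe set, from a non-stretched signal of 29.1 that lay just above the floor, and differed by only 0.08 on the log2 scale in the other. GAL, the neuropeptide galanin, was above the floor in the stretched array only and was at least 17.2-fold higher, and the activating E2F family member E2F2 was at least 9.95-fold higher. GRIN2A, SH2D5 and C12orf56 were likewise above the floor in the stretched array only, at least 9.60-fold, 9.02-fold and 7.68-fold higher, although a dimmer GRIN2A probe set differed by 0.80.

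In the other direction, STEAP4, a metalloreductase, was 15.5-fold lower in the stretched array (958 to 61.6) and NDRG1, a gene induced by hypoxia and differentiation, was 15.3-fold lower (1455 to 94.8). CRP, the acute-phase C-reactive protein, was 12.9-fold lower, with probe sets at -3.69 and -2.61 on the log2 scale. RGL1, RCAN2 and the interferon-induced GTPase MX1 were each 11.1-fold lower. JDP2, an AP-1 repressor, was 10.4-fold lower, CAPN5 10.3-fold, BTN3A1 10.1-fold, TP53INP1 9.79-fold and TNFAIP2 9.62-fold lower. ABHD4 was 9.80-fold lower in its brightest probe set, and its other probe set differed by -0.45 on the log2 scale. The other BTN3A1 probe set differed less than the brightest. The stretched signals of BTN3A1, TP53INP1 and TNFAIP2 lay just above the floor (32.8, 32.6 and 30.7), so the size of these folds is uncertain. Above the floor in the non-stretched array only were IFI44L (at least 14.1-fold lower in the stretched array), the mTOR inhibitor DEPTOR (at least 10.9-fold), CNTN4 (at least 10.5-fold, -0.77 in its other probe set), MKX (at least 9.83-fold) and TRIM22 (at least 9.42-fold).

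Genes of the cell cycle were higher in the stretched array as a group. All 24 measured genes of the G1/S and replication list were at least 2-fold higher, with a median log2 difference of 2.29 (4.87-fold), above all 10000 random lists. MCM10, a replication initiation factor, was 10.8-fold higher (151.0 to 1638) and its 3 probe sets agreed within 3.43 to 3.63 on the log2 scale. CDC45, part of the replicative helicase, was 9.41-fold higher and CCNE2, cyclin E2, 8.97-fold higher. GINS2 was 9.41-fold higher in its brightest probe set, while another of its probe sets differed by -0.33. Of the 25 measured G2/M genes, 23 were at least 2-fold higher and none was lower, with a median of 1.79 (3.45-fold), also above all random lists. The mitotic kinases AURKB and PLK1 were 6.26-fold and 5.32-fold higher, and the motor proteins KIF23 and CENPE 5.58-fold and 5.47-fold higher; a second AURKB probe set differed by only 0.29. CDC25A, the phosphatase that activates cyclin-dependent kinases at S-phase entry, was 10.9-fold higher, with its dimmer probe sets down to 1.25, and the condensin subunit NCAPH 11.7-fold higher. Probe sets of replication-dependent histones did not move with these lists: 4 of 11 measured members were at least 2-fold lower and 1 at least 2-fold higher. Their median of -0.34 lay inside the random range (4.69th percentile). How well the labelling captured histone transcripts was not tested. These values therefore do not decide whether histone expression followed the replication genes. Without probe sets ending in _x_at or _s_at the median of the 7 members left was -0.07 (37.6th percentile), and with no floor it was -0.22. With the floor at the 75th percentile it was -0.57 (0.47th percentile), below the random range, as was the list's mean of -0.60. H2AC6 was 3.61-fold, H4C8 3.13-fold, H2BC4 2.83-fold and H2BC5 2.70-fold lower, the first by a probe set ending in _s_at and the last by one ending in _x_at.

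**Figure D2:**
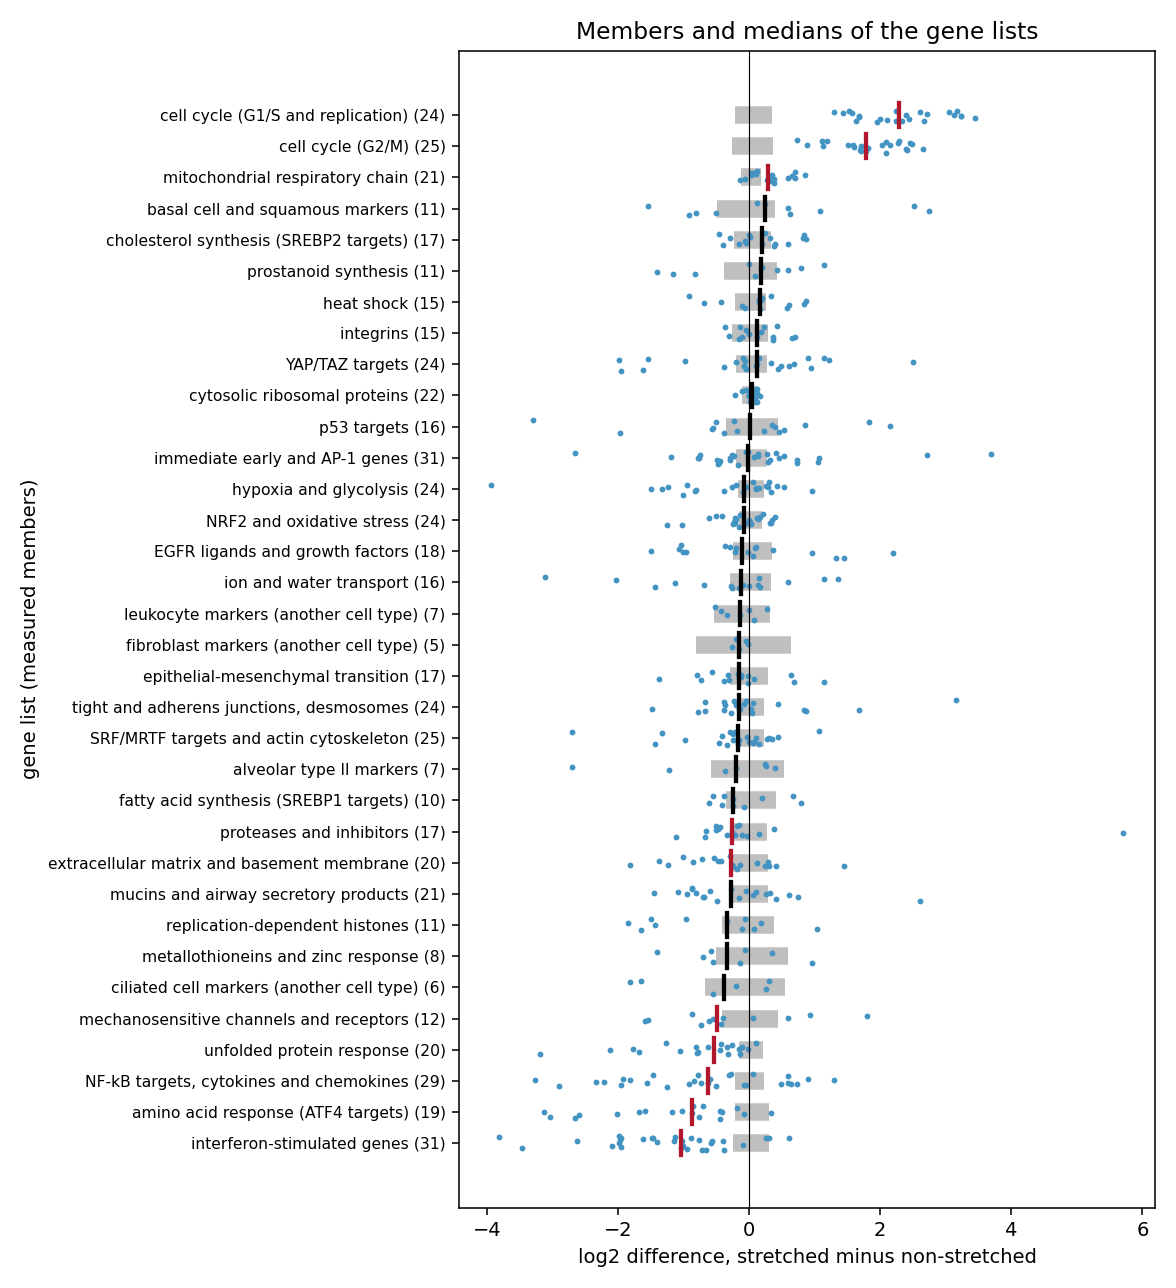
Log2 difference (stretched minus non-stretched, x axis) of each measured member (blue points, spread vertically for display) of the 34 gene lists with at least 5 measured members (y axis, number measured in brackets). Thick vertical marks are list medians, red where they fall outside the grey bar that holds the central 95% of 10000 matched random lists; the 2 cell cycle lists (medians 2.29 and 1.79) and the interferon list (median -1.04) lie farthest out.

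Interferon-stimulated genes were lower in the stretched array. Of 31 measured, 18 were at least 2-fold lower, none was at least 2-fold higher and 13 differed by less, and the median of -1.04 lay below all random lists. The antiviral effector IFIT2 was 6.16-fold lower in its brightest probe set (-0.93 on the log2 scale in the other), and IRF9, the DNA-binding subunit of the interferon-activated complex ISGF3, was 4.25-fold lower (1295 to 304.6). NF-kB targets, cytokines and chemokines had a median of -0.62, below all random lists, with 10 of 29 at least 2-fold lower and 1 at least 2-fold higher. The median was -0.28 with the floor at the 75th percentile and also without probe sets ending in _x_at or _s_at, still below the central 95% but not below all random lists. The leukocyte adhesion molecule ICAM1 was 7.46-fold lower, with 3 probe sets between -2.97 and -1.75 on the log2 scale. The chemokine CCL20 was 5.05-fold lower (2695 to 533.8) and the death ligand TNFSF10 (TRAIL) 4.65-fold lower. Of the 29 members, 8 lay above 0 and 21 below 0 in the brightest probe set. Among genes named outside the rule after their values were seen, IL1RN, the interleukin-1 receptor antagonist, was at a log2 difference of 1.29. The bright chemokines CXCL5 and CXCL8, named in the same way, were at -0.04 and -0.31.

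Genes of the amino acid response and the unfolded protein response were also lower. Of 19 measured targets of the transcription factor ATF4, 9 were at least 2-fold lower, none was at least 2-fold higher, and 18 lay below 0, with a median of -0.87 below all random lists. CTH, which makes cysteine from cystathionine, was 8.24-fold lower with probe sets at -3.15 and -3.04. SESN2, a stress-induced inhibitor of mTORC1, was 6.02-fold lower, ALDH1L2 was 6.31-fold lower in its brightest probe set (-0.31 in the other), and the glutathione-degrading enzyme CHAC1 was at least 8.74-fold lower. Of 20 unfolded protein response genes, 6 were at least 2-fold lower and none higher (median -0.54, below all random lists). DDIT3 (CHOP), a stress-induced transcription factor, was 9.12-fold lower (1948 to 213.6). HERPUD1, SEL1L and DNAJB9, of endoplasmic-reticulum-associated degradation and folding, were 4.37-fold, 3.42-fold and 3.20-fold lower. Heat shock genes did not stand apart: none of 15 differed 2-fold in the brightest probe set and the median was 0.17. HSPA4L was 1.83-fold higher in that probe set (1.18 on the log2 scale in its other) and HSPB1 1.62-fold lower. Of 24 hypoxia and glycolysis genes, 5 were at least 2-fold lower and none higher, with a median of -0.07 inside the random range. NDRG1, the mitophagy receptor BNIP3L (2.82-fold), the peptide hormone ADM (2.51-fold) and ANKRD37 (2.35-fold) were lower. The mean of this list, -0.38, differed from its median and lay at the 0.14th percentile of random means.

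Lists tied to mechanical loading were mixed. YAP/TAZ targets had a median of 0.12 inside the random range, with 3 of 24 at least 2-fold higher and 4 at least 2-fold lower. BIRC5 (survivin), which is also a mitotic gene, was 5.64-fold higher, while ARHGEF17 was 3.96-fold (to 34.6, near the floor), TGFB2 3.08-fold and RBMS3 at least 3.85-fold lower. Of other widely used YAP targets, named outside the rule, CCN1 and CCN2 were at -0.39 and -0.05, and ANKRD1, AXL and DLC1 were at 0.95, 1.22 and 1.15. Immediate early and AP-1 genes had a median of -0.02 and a mean of 0.11, opposite in sign, with 4 of 31 at least 2-fold higher and 2 lower: KLF2 was 6.53-fold higher beside FOSL1, and ATF3 and EGR1 were 6.27-fold and 2.27-fold lower. SRF/MRTF targets and actin genes had a median of -0.17 at the 2.96th percentile, just inside the random range. It was 0.09 (76.1st percentile) without probe sets ending in _x_at or _s_at, and -0.03 with the floor at the 75th percentile or with probe sets averaged. The list's mean of -0.25 lay below the random range of means. The contractile genes MYL9, TAGLN and CALD1 were 6.47-fold (to 32.0, just above the floor), 2.70-fold and 2.51-fold lower and PDLIM7 was 2.09-fold higher. Integrin and adhesion genes had a median of 0.12 inside the random range, and none of 15 differed 2-fold in its brightest probe set. By that probe set PXN was 1.63-fold higher (0.08 on the log2 scale in its other probe set), and ITGA1, ITGA6 and ITGAV were at 0.65, 0.43 and -0.37, with another ITGA1 probe set at -0.09 and another ITGA6 probe set at 1.20. CD44, named outside the rule, was at 0.36 in its brightest probe set, but its 10 probe sets ranged from -0.22 to 2.09 with a median of 1.08.

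Matrix genes had a median of -0.28 below the random range, with 4 of 20 at least 2-fold lower and 1 higher. The collagen cross-linking enzyme LOX was 3.52-fold lower, fibronectin FN1 2.58-fold lower (a probe set ending in _x_at) and the collagen prolyl hydroxylase P4HA1 2.36-fold lower. COL6A1 was 2.74-fold higher, with another probe set at -0.09. Without probe sets ending in _x_at or _s_at, 10 matrix members were left, and their median was -0.06 and inside the random range. Proteases and inhibitors had a median of -0.26 (1.89th percentile), but their mean was 0.03 because of MMP1, and the list was inside the random range when probe sets were averaged (-0.18); MMP15 was 2.16-fold, MMP7 1.60-fold and TIMP2 1.58-fold lower. Mechanosensitive channels and receptors had a median of -0.50 (0.98th percentile), with 2 of 12 at least 2-fold lower and 1 higher. The ATP-gated channel P2RX4 was 3.01-fold and TRPC1 2.92-fold lower (another TRPC1 probe set at -0.23), whereas ADORA2B, an adenosine receptor, was 3.47-fold higher and P2RY2 1.90-fold higher near the floor. PIEZO1 and TRPV4, named outside the rule, were at -0.74 and -0.44, TRPV4 near the floor. This list was inside the random range when probe sets were averaged (-0.22), without probe sets ending in _x_at or _s_at (-0.17), with no floor (-0.42) and by its mean (-0.28). Growth factors and EGFR ligands had a median of -0.11 inside the random range, with 3 of 18 higher (FGFBP1 4.59-fold, FGF2 2.74-fold, EGFR 2.51-fold, with another EGFR probe set at 0.19) and 4 lower, among them PDGFB at 2.82-fold (_x_at).

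Ion and water transport genes had a median of -0.12 inside the random range, with 4 of 16 at least 2-fold lower and 2 higher, and a mean of -0.35 at the 1.32nd percentile. CFTR, the chloride channel mutated in cystic fibrosis, was 2.69-fold lower (5924 to 2199), with log2 differences of -1.43 in its brightest and at most -1.32 in each of its 3 probe sets. SCNN1A, the alpha subunit of the epithelial sodium channel, was 8.64-fold lower in its brightest probe set but differed by -0.05 in the other. KCNE3 was at least 4.09-fold lower, with its other probe set at 0.15, and the water channel AQP5 was 2.55-fold higher. Junction genes had a median of -0.16 (2.85th percentile, inside the range) and a mean of 0.04: the pore-forming claudin CLDN2 was 8.93-fold higher (from 34.2, near the floor), the connexin GJB2 at least 3.18-fold higher, TJP3 2.80-fold lower and CLDN18 1.82-fold higher. Mucins and secretory products had a median of -0.28 (2.59th percentile, just inside the range). The list stood lower in 4 of the alternatives, which were the loess trend removed, the floor at the 75th percentile, probe sets averaged, and probe sets ending in _x_at or _s_at left out. MUC1 was 2.73-fold, WFDC2 2.12-fold and PIGR 1.93-fold lower. MUC5AC, a gel-forming airway mucin, was at least 6.10-fold higher in a probe set ending in _s_at, and a probe set ending in _x_at differed the same way by nearly as much. The third measured probe set, which has neither ending, was at -0.97. Among basal and squamous markers (median 0.25, inside the range), KRT13, SPRR3 and IVL were above the floor in the stretched array only, at least 6.71-fold, 5.70-fold and 2.11-fold higher, and KRT14 was 2.92-fold lower. Epithelial-mesenchymal transition genes had a median of -0.16 inside the range: S100A4 was higher by 1.14 on the log2 scale, FN1 was lower as among the matrix genes, and ESRP1 and CDH2 were 1.74-fold and 1.66-fold lower. Of the alveolar type II markers (median -0.19, inside the range), SLC34A2 was at least 6.48-fold and LAMP3 2.32-fold lower, with LPCAT1 and NKX2-1 at 0.39 and -0.36.

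Respiratory chain genes were higher by a small amount: 19 of 21 lay above 0 and none differed 2-fold in the brightest probe set (other probe sets of COX5A, COX4I1 and NDUFB8, named outside the rule, were at 1.51, 1.46 and -0.76), and the median of 0.29 lay at the 99.9th percentile and was 0.18 with the arrays centred on the 75th percentile. ATP5MC1, NDUFA9, NDUFS3 and CYC1 were 1.81-fold, 1.63-fold, 1.62-fold and 1.57-fold higher. Cytosolic ribosomal proteins had a median of 0.05 inside the range, and -0.06 with the arrays centred on the 75th percentile. The largest difference among 22 in the brightest probe set was RPS25 at -0.21. Other probe sets of RPL18 and RPS15 were at 0.53 and 0.30. The brightest probe sets of these 3 genes read above the 99th percentile of both arrays, where saturation could hide a change. Cholesterol synthesis (median 0.20), fatty acid synthesis (-0.25), oxidative stress (-0.08), metallothionein (-0.34), prostanoid (0.18) and p53 target (0.02, mean -0.05) lists did not stand apart. In these, ACAT2, EBP and MVD were 1.82-fold, 1.79-fold and 1.76-fold higher (another EBP probe set at -0.20), ELOVL6 and FASN 1.73-fold and 1.59-fold higher, SREBF1 and ACSS2 1.53-fold and 1.47-fold lower (another SREBF1 probe set at 0.49), and SOD2, HMOX1 and MT1F (_x_at) 2.39-fold, 2.04-fold and 2.65-fold lower. The cyclooxygenase PTGS2 was 2.65-fold and ALOX5 2.24-fold lower, and PTGER4 was 2.21-fold higher. Among p53 targets, AEN and DDB2 were 4.46-fold and 3.56-fold higher, and beside TP53INP1 the stress cytokine GDF15 (_x_at) was 3.91-fold lower.

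Fibroblast, endothelial and leukocyte markers were dim in both arrays. Of the fibroblast, endothelial and leukocyte markers, only 5, 2 and 7 were measured (medians -0.16, 0.25 and -0.15), and none of these differed 2-fold in its brightest probe set. The fibroblast collagen COL1A1 (_x_at) was at -0.26 in that probe set and at -2.52 in another, and in the third measured probe set it went from 149.2 to below the floor. No probe set of these 3 groups' 34 markers on the array exceeded 174.3 in the non-stretched array, whose 75th percentile was 231.1. Ciliated cell markers had a median of -0.38 inside the range over 6 genes, with CAPS, named outside the rule, bright in both arrays (1072 and 931.3), TPPP3 3.53-fold lower and DNAH5 3.12-fold lower in one probe set and higher by 1.12 on the log2 scale in another. The 3′ minus 5′ log2 difference of the ACTB control was 0.06 in the non-stretched and 0.02 in the stretched array, and that of the GAPDH control was -0.19 and -0.21. For the 18S ribosomal RNA control it was -1.29 and -1.93. The 3′ and 5′ parts of the ISGF3A control read 1999 and 50.7 in the non-stretched array and 1149 and 20.2 in the stretched array.

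**Figure D3:**
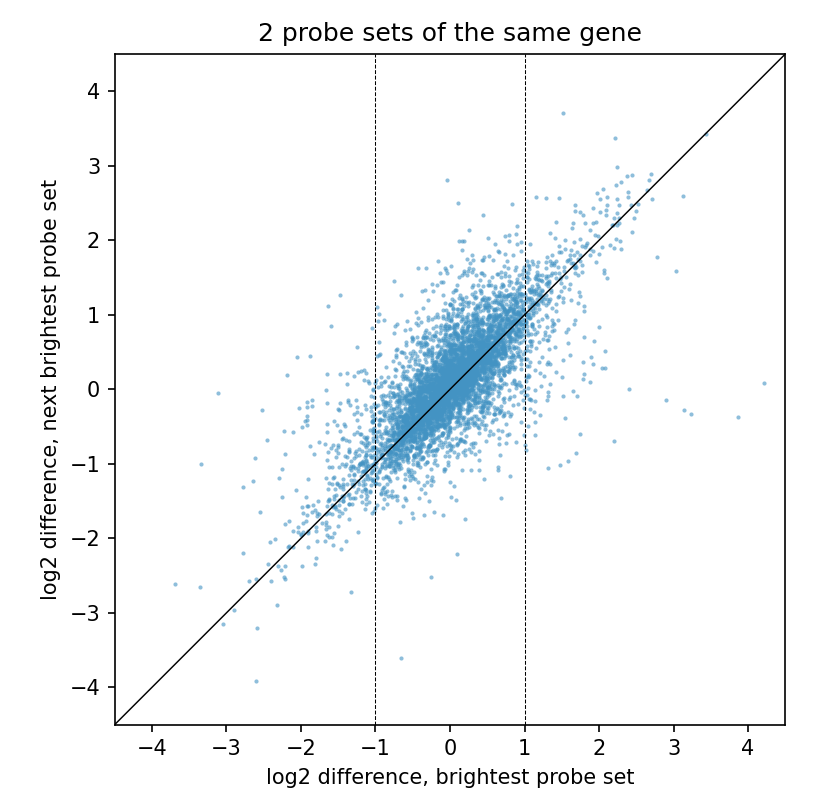
Log2 difference (stretched minus non-stretched) of the brightest (x axis) and next brightest (y axis) probe set of each of 5818 genes with 2 or more probe sets above the floor in both arrays; the solid line marks equality and the dashed lines a 2-fold difference of the brightest. Of the 740 genes outside the dashed lines, 686 had the same direction in both probe sets.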

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

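Apart from the scaling tests and the other-cell-type test on the brightest probe set, the tests below were chosen after the result was seen. With 1 array per group no test for an outlying sample applied. A control probe set for the middle part of 28S ribosomal RNA, which belongs to no gene comparison, was 8.12-fold higher in the stretched array (657 to 5338). The 5′ part was 1.88-fold higher, and the 3′ part was below the floor in both arrays (1.36 and 11.9). Among 3137 measured probe sets unnamed here, 216 were at least 2-fold higher and 132 at least 2-fold lower in the stretched array. Of the 13453 measured named genes, 1046 were at least 2-fold higher and 1008 at least 2-fold lower. The shares among unnamed probe sets were not above those among named genes. These shares are unlike measures, since every unnamed probe set was counted but only the brightest probe set of each named gene. Why more unnamed probe sets were higher than lower was not tested.

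Cell cycle genes were higher in the stretched array, with list medians of 2.29 and 1.79. Scaling or an intensity-dependent trend is argued against, since the lower of the 2 medians stayed at 1.68 or above under the 3 other normalizations. Both medians also stayed beyond the random range under quantile normalization and loess. That range adds little here, because random lists matched on mean expression would share an intensity-dependent trend. RNA degradation stays open. The 3′ minus 5′ difference of ACTB and GAPDH changed by at most 0.043. These control probe sets read 9081 or more, above the 99th percentile of both arrays, where saturation could hide a change. The 3′ minus 5′ difference of the 18S ribosomal RNA control changed by -0.64 (3′ part 2877 to 1693). It reads ribosomal and not messenger RNA, so its change does not decide whether messenger RNA was degraded. The 18S control stood in for the dimmer ISGF3A control planned beforehand. The 3′ part of ISGF3A went from 1999 to 1149. Its 5′ part went from 50.7 to 20.2, below the floor, so its 3′ minus 5′ change is uncertain. Growth state of the 2 cultures apart from stretch (density, medium, time since plating) cannot be told apart from stretch, because there was 1 culture per group. A biological effect of stretch, which the design names, is likewise untested by replication.

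Interferon-stimulated and NF-kB genes were lower in the stretched array, with medians of -1.04 and -0.62. Scaling or an intensity-dependent trend is argued against, since the higher of the 2 medians was -0.61 or lower under each of the 3 other normalizations. Both medians also stayed below the random range under quantile normalization and loess, which adds little for the reason given for the cell cycle lists. Leukocytes, fibroblasts or endothelial cells in the non-stretched sample are argued against as the source, because 0 of 34 markers of these types exceeded the array's 75th percentile in any of 88 probe sets; 2 COL1A1 probe sets were at least 2-fold lower in the stretched array (-2.52 in one, and from 149.2 to below the floor in the other), but COL1A2 read 28.8 and COL3A1 was below the floor (both named outside the rule). A difference between the 2 cultures apart from stretch, and stretch itself, stay open. An exchange of the 2 labels, which would turn every direction, was not tested.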

How the results depend on the processing

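No paired analysis was possible because each group holds 1 array, and no replicate could be left out. The choices listed under processing were fixed before the data were examined, except the count of genes with every probe set 2-fold different and the spike-in medians under other normalizations. The counts of genes at least 2-fold higher in the stretched array and genes at least 2-fold lower in the stretched array (1046 and 1008) became 549 and 394 with the floor at the 75th percentile, 2304 and 2374 with no floor, 2405 and 2249 at a 1.5-fold threshold, 386 and 378 at a 3-fold threshold, and 220 and 175 when every one of at least 2 probe sets had to differ 2-fold; with the floor at the 25th percentile they were 1435 and 1524. Centring on the 75th percentile gave 853 higher and 1218 lower and shifted the median of all genes to -0.10. No gene changed direction between the main calls and the calls of the 8 alternatives in normalization, floor and probe sets. The SD of a probe set was 0.22 with the floor at the 75th percentile, where 11 lists in place of 7 stood lower, the others being mucins, junctions, metallothioneins and histones. Spike-in medians were -0.19 (quantile), -0.22 (centring) and -0.21 (loess). With the floor at the 75th percentile, list medians moved to -0.28 for NF-kB, -0.39 for proteases, 1.23 for G2/M, 2.04 for G1/S and -0.88 for interferon. Without probe sets ending in _x_at or _s_at they were -0.28 for NF-kB, -0.064 for matrix (inside the random range), -0.44 for proteases, -0.74 for the amino acid response, -1.46 for interferon and -0.17 for mechanosensitive channels (inside). Centring gave -0.65 for the unfolded protein response and 0.18 for the respiratory chain. Means in place of medians were -0.81 for the unfolded protein response, -1.23 for the amino acid response, -1.22 for interferon and 0.035 for proteases, which reversed through MMP1 and was inside the range; averaging probe sets gave -0.22 for mechanosensitive channels and -0.18 for proteases, both inside the range. With means, the SRF, hypoxia, ion transport and histone lists also stood lower, and mechanosensitive channels (-0.28) were inside the range, as they were with no floor. Mucins stood lower in 4 settings. Among lists not standing apart, medians changed sign in at least 1 setting for the immediate early, SRF, growth factor, metallothionein, p53, ion transport, alveolar type II, basal cell, ribosomal, endothelial, leukocyte and ciliated lists. The 2 cell cycle, respiratory chain, interferon, NF-kB, amino acid and unfolded protein lists stood apart the same way under 8 alternatives. Centring moves every gene alike and tests no percentile. Quantile normalization and loess test it little, since the random lists were matched on mean expression. Of the named genes at least 2-fold different, 2 reversed: CHAC1 was 0.0069 with the floor at the 75th percentile, which sets its stretched value to 249.0, above its non-stretched signal, and MUC5AC was -0.97 without probe sets ending in _x_at or _s_at. Of the other values of named genes under alternatives, 1114 stayed within 1 SD of a probe set and 116 moved further; reversal was looked for only in genes at least 2-fold different. Beyond these constructions the cause was not tested. Signal near the floor limits small differences and the size of large folds with 1 signal near it.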

Other observations

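The gene lists and genes named in this part were chosen after the results above were seen, and the directions for growth arrest were written down before those lists were computed. Genes of homologous recombination and the Fanconi anaemia pathway followed the replication genes: 9 of 10 measured were at least 2-fold higher in the stretched array, with a median log2 difference of 2.04 above all 10000 random lists. BRIP1 and RAD54L, of DNA strand repair, were at 2.46 (0.78 in another BRIP1 probe set) and 2.39, and ATR was at -0.40. Nucleotide synthesis genes had a median of 0.82, above all random lists, with all 13 above 0 in the brightest probe set (another UMPS probe set at -0.10). Of these, SHMT1 was above the floor in the stretched array only (48.2). Thymidine kinase TK1 was at 2.25 and CTP synthase CTPS1 at 1.51. Proteasome subunits were higher by a small amount, with 17 of 18 above 0 in the brightest probe set and a median of 0.26 (99.5th percentile). They ranged from -0.15 for PSMA4 to 0.66 for PSMD11, and other probe sets of PSMD11 and PSMB2 were at 1.84 and 1.21.

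Acute-phase and complement genes were lower: all 10 measured lay below 0 in the brightest probe set, 5 were at least 2-fold lower, and the median of -0.93 was below all random lists. The fibrinogen genes FGA, FGB and FGG were above the floor in the non-stretched array only, and near it (34.9, 31.0 and 38.4). With the floor their differences could only lie below 0, so they add little to this count. C1S, C3 and CFB, of the complement cascade, were at -2.37, -2.27 and -1.80, although another CFB probe set was at 0.32. Genes of MHC class I antigen presentation were lower by less, with a median of -0.30 (0.995th percentile) and none 2-fold different in its brightest probe set. All 11 lay below 0 in that probe set, but TAP2 was at -0.15 there and at 0.64 in the median of its 3 probe sets, and TAPBP and ERAP1 each had a probe set above 0. HLA-B, HLA-C, HLA-E and HLA-F were each read by a probe set ending in _x_at, which can bind related genes, so they may not be separate readings. Those of HLA-B and HLA-C, and that of B2M, read above the 99th percentile of both arrays, where saturation could distort a difference. NLRC5 was above the floor in the non-stretched array only, and just above it (29.4). This list shares its regulation by interferon with the interferon-stimulated list, so the 2 are not independent.

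The lower amino acid response genes, beside higher replication genes, raise the hypothesis that the non-stretched culture was nearer growth arrest or nutrient limitation at harvest than the stretched culture. FOXO targets and quiescence genes should then be lower in the stretched array, and their median was -1.06, below all random lists, with 10 of 19 at least 2-fold lower. CCNG2 and KLHL24 were at -2.70 and -2.60, each with a dimmer probe set above 0, and TXNIP was the exception at 1.78 (0.36 in its other probe set). FBXO32, counted as lower at -1.31, had a median of -0.19 over its 5 measured probe sets, which reached 0.89. Nucleolar ribosome biogenesis genes should be higher, and all 18 lay above 0 in the brightest probe set with a median of 0.80 (another NCL probe set at -0.77); UTP20 and MRTO4 were at 1.54 and 1.40. Lysosome and autophagy genes should be lower, and their median was -0.52 (0.01st percentile), with ULK1 and WIPI1 at -1.80 and -1.65 and GLA at 1.02. Each list moved in the direction written down beforehand. These lists were, however, chosen after the cell cycle difference was seen, and they can follow growth in either culture. Their directions therefore cannot tell arrest of the non-stretched culture from faster growth of the stretched culture. The lower unfolded protein response genes were not part of these predictions. Whether stretch or another difference between the cultures set the growth state is untested.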
